A study of Enchytraeus crypticus with 48 samples.

How the data were processed

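RNA abundance was measured on microarrays in the potworm Enchytraeus crypticus, a small white annelid that lives in soil. Adult worms with a visible clitellum, the reproductive band of the body wall, were kept in LUFA 2.2, a natural reference soil used in soil toxicity tests. The soil held no added zinc or zinc at the EC10 or the EC50, and worms were sampled on days 1, 2, 3 and 4. EC10 and EC50 are by name the concentrations with 10% and 50% effect on a measured response. The response behind them and the amounts of zinc are not given in the sources used here. Each sample was the RNA of 1 pool of 10 worms, with 4 pools in each of 12 groups, 48 samples in all. The labels do not say whether pools of a group came from separate soil containers, so p-values measure only the spread between these pools.

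Per the labels, RNA was amplified and labelled with Cy3 or Cy5 for Agilent 2-colour arrays. Each channel was 1 sample, so that 2 samples shared each of 24 arrays, on 6 slides of 4 arrays. In every group 2 pools carried Cy5 and the others Cy3. Pools were placed on arrays as an interwoven loop, per the labels, with no reference RNA. Each sample was matched to its value column through the array named in its label, and the red column of an array was taken as its Cy5 channel.

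The deposited table holds log2 intensities of 172824 spots, which are 86412 probes printed on 2 spots each. Scanning used Agilent Feature Extraction 9.5.1.1 and limma was used, per the submitters' processing notes. The order, background correction and normalization of those steps are not given in the sources used here. Deposited values ran from 4.91 to 19.56 on the log2 scale. In 46 of 48 channels at least 50% of the values between 5 and 6.5 were the log2 of a whole number within 0.00051, against 2.6 to 3.9% by chance, so most channels carry intensities that were not rescaled. The 75th percentile of a channel ran from 5.20 to 7.11, and from 6.01 to 7.11 in Cy5 against 5.20 to 6.26 in Cy3. The plan fixed before the data were examined took the values as deposited, because the table is named as normalized. Since brightness differed this much between channels, quantile normalization over all 48 channels became the setting of every result below, a choice made after seeing the distributions and before any test. The deposited values were kept as an alternative.

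The 2 spots of a probe were averaged after normalization. Over all spot pairs the correlation within a channel was 0.9735 to 0.9934. No pair of channels held identical values. The table has no background or detection flags, so no probe was left out. A log2 level of 6, an intensity of 64, is used below only to describe brightness. Between 13.8 and 47.4% of the spots of a channel were above it. Values start near 4.91, an offset that makes log2 changes of dim probes understate the change in RNA.

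Each comparison used limma 3.58.1 in R 4.3.3. A linear model with 12 group means and a dye term was fitted to every probe over all 48 samples. The 2 samples of an array were allowed to correlate, with a consensus correlation of 0.25 estimated on 4000 random probes. Residual degrees of freedom were 35 and the prior added 3.8. Moderated tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over 86412 probes for each comparison. A probe is called at an adjusted p under 0.05. The comparisons were EC10 and EC50 against the controls of each day and on the mean of 4 days, EC50 against EC10 on that mean, the difference of each zinc effect between days, and control animals between days. The dye effect was called on 14390 probes, 16.7% of them. The number of arrays limits the precision of every value. In simulated data with known changes on the real design, EC50 against control on day 3 recovered 74.6% of 1.5-fold, 91% of 2-fold and 98.5% of 4-fold changes over 86412 probes. On the mean of 4 days these shares were 95.5, 97 and 100%. The changes were added in full to the log2 levels of random probes, whereas the offset shrinks real changes of dim probes. The simulated noise was normal and had no correlation within slides. These shares may thus be too high for real changes in RNA.

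The table does not pair probe IDs with gene names, and no annotation of the array was used here. The 21 gene lists fixed before the data were examined were not tested for that reason. Probes are named by ID, without the ending _PI427420766_a that all of them share. The naming rule was fixed before the data were examined. For each comparison it named the 2 called probes with the largest rise and the 2 with the largest fall. Only probes that held their direction over all days, or in all treated pools for a single day, could be named. This choice favours probes with a steady direction over days or pools. For the test between days the rule named the 2 probes with the lowest p. Any other probe named was chosen after its values were seen.

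Samples on one slide deviated together. The mean correlation of residuals was 0.46 for samples of one array, 0.26 for other arrays of one slide and -0.05 between slides. Slide was therefore also fitted as a fixed block. Other alternatives were the values as deposited, channels centred on their median, loess within arrays with quantile scaling of their mean levels, each comparison fitted on its own day or groups alone, models without dye or array, array or replicate number as a fixed block, probes above the median level, channels with a 75th percentile under 5.6 left out, estimated sample weights, and each pool left out in turn. Comparisons that share control pools were set beside 10 simulations of unchanged groups, the overlap of independent lists, and the value with the controls split between them.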

Results

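Whole-animal RNA of 48 pools of 10 potworms was measured on 24 two-sample arrays. The pools formed 12 groups of 4, control, EC10 and EC50 zinc on each of days 1 to 4. Every pool gave a value for each of 86412 probes. Brightness stood in place of depth, and 13.8 to 47.4% of the spots of a channel were above an intensity of 64. The series asks which transcripts change under zinc toxicity, and its design allows the zinc effect to be followed over concentration and time. Levels are quantile-normalized log2 intensities, group values are means ± SD over 4 pools, and changes are model estimates ± SE.

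At the EC50, averaged over the 4 days, 285 probes differed from the controls, of which 93 rose and 192 fell. The largest rise was that of probe CUST_11333, by 3.25 ± 0.21 on the log2 scale (adjusted p = 2.6e-14). It lay at 5.15 ± 0.16 in control animals on day 1 and 5.48 ± 0.10 on day 4, below an intensity of 64 in all control pools, so the log2 change is not given as a fold, and at 8.14 ± 0.19 and 9.42 ± 0.54 in EC50 animals on the same days. Probe CUST_19204 rose by 2.27 ± 0.12 (adjusted p = 2.7e-16), from 5.94 ± 0.14 to 8.02 ± 0.23 on day 1. It was dim in control animals too, with means of 5.94, 5.99, 5.62 and 5.96 on days 1 to 4. The largest falls were those of CUST_16020, by 1.28 ± 0.24 (adjusted p = 0.0042), and CUST_16751, which fell by 1.09 ± 0.11 (adjusted p = 5.3e-08).

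Most changes at the EC50 were small. The median of the probes that rose was 0.52 and that of the probes that fell was -0.39, while 15 rose and 3 fell by at least 2-fold. The probes that rose had medians of 0.20, 0.52, 0.77 and 0.54 on days 1 to 4, and 81 of the 93 lay above the controls on all 4 days. The probes that fell had medians of -0.22, -0.39, -0.48 and -0.40, and 173 of the 192 lay below the controls on all 4 days. Both sets were called on the mean of the same days, which favours one direction on each day. The share that rose depended on the scaling: 63 rose and 3 fell with the values as deposited, 134 and 13 with channels centred on their median, and 200 and 243 with loess. With slide as a block 322 probes were called, and within the 6 slides 76.8 to 99.3% of the 285 probes kept their direction, with medians of 0.16 to 0.56 in that direction, in the pools that had selected them. The count was 66 with the deposited values and 109, 110, 168 and 110 without the pools numbered 1, 2, 3 or 4. With the deposited values neither CUST_16020 (adjusted p = 0.21) nor CUST_16751 (adjusted p = 0.086) was called. Over 16 other fits CUST_16020 was not called in 6 and CUST_16751 in 1, with changes of -1.50 to -1.01 and of -1.17 to -0.84.

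**Figure D1:**
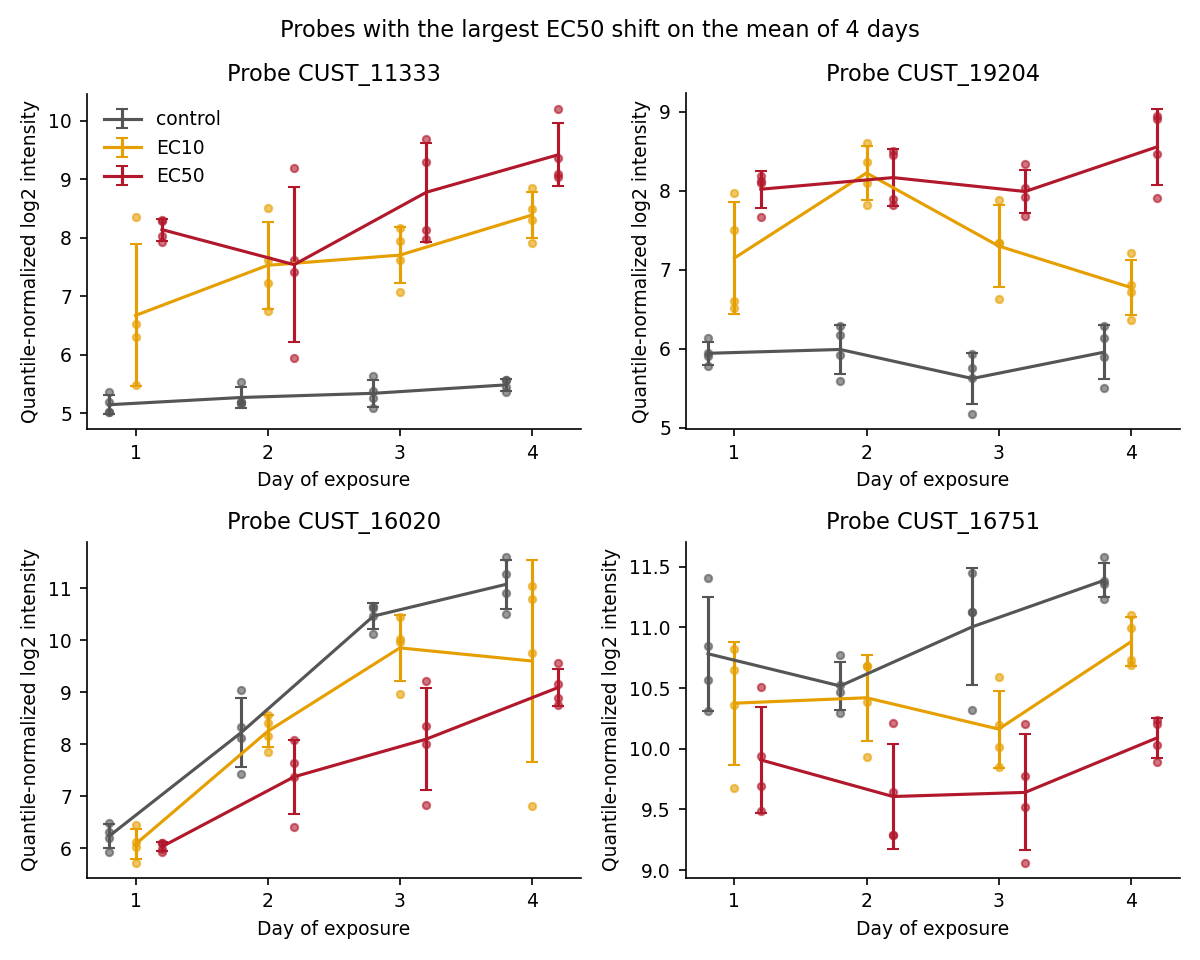
Levels of 4 probes in each pool (points), with group means and SD (lines and bars, n = 4), by day of exposure on the x axis and quantile-normalized log2 intensity on the y axis. CUST_11333 and CUST_19204 lay above the controls in both zinc groups, whereas CUST_16020 was higher on day 4 than on day 1 in all 3 conditions and lay at 11.07 in control and 9.09 in EC50 animals on day 4.

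On single days the EC50 was set against controls of the same day, to ask when the response could be seen. On day 1, 7 probes rose and none fell at an adjusted p under 0.05 in limma. There 2044 probes, 2.37% of all, had an unadjusted p under 0.05, fewer than unchanged probes alone would give. The day 1 count was 1 with the deposited values and 1 with the samples of that day alone in the fit. The rises were led by CUST_11333 (3.04 ± 0.40) and CUST_11849 (2.14 ± 0.25), and 6 of the 7 probes were also called on each later day. On day 2, 16 probes rose and 14 fell. CUST_11333 rose by 2.58 ± 0.42 and CUST_19204 by 2.19 ± 0.25, while CUST_18519 fell by 1.62 ± 0.25 and CUST_41163 fell by 1.40 ± 0.27. On day 3, 56 probes rose and 60 fell, with CUST_11333 (3.45 ± 0.40) and CUST_52260 (2.96 ± 0.54) at the top. CUST_16020 fell by 2.39 ± 0.48 and CUST_18614 fell by 1.57 ± 0.29. On day 4, 19 probes rose and 15 fell. CUST_11333 rose by 3.95 ± 0.42 and CUST_19204 rose by 2.59 ± 0.25. CUST_18614 fell by 2.20 ± 0.30 and CUST_15773 fell by 1.34 ± 0.25. Across 20 other fits each, CUST_41163 on day 2 was called in 8 and CUST_16020 on day 3 in 11, with changes of -1.55 to -0.80 and of -2.83 to -1.91, while CUST_11333 was called in all 20 on days 3 and 4. The probes that fell depended on the scaling on single days too: on days 2, 3 and 4, 18, 12 and 10 rose and 0, 0 and 1 fell with the deposited values, and 25, 35 and 15 rose and 0, 1 and 1 fell with median centring.

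In all, 149 probes were called at the EC50 on at least 1 day, 125 of them on 1 day and 6 on all 4 days. These 6 were CUST_4409, CUST_11333, CUST_19204, CUST_11849, CUST_44783 and CUST_49496, which all rose and were singled out after their values were seen. The 116 probes of day 3 had the same direction for 89 probes on day 1, 100 on day 2 and 95 on day 4, where the controls were other pools, with medians of 0.12, 0.30 and 0.32 against 0.77 on day 3. No probe was called for a difference of the EC50 effect between days by limma (lowest adjusted p = 0.113). An unadjusted p under 0.05 was seen for 5639, 6.53% of all, where unchanged probes alone would give a share near 0.05. Loess called 3 probes for this difference and sample weights 26. The day 3 count fell to 12 with the values as deposited, to 36 with median centring, to 9 with the samples of that day alone in the fit and to 62 without the dim channels. It was 156 with slide as a block and 284 with loess. Within each slide that held EC50 and control pools of a day, all probes called on that day kept their direction, in the pools that had selected them. Leaving out 1 pool gave 64 or 57 probes without control pool 1 or 2 of that day, and 46, 75 or 72 without EC50 pool 1, 3 or 4.

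**Figure D2:**
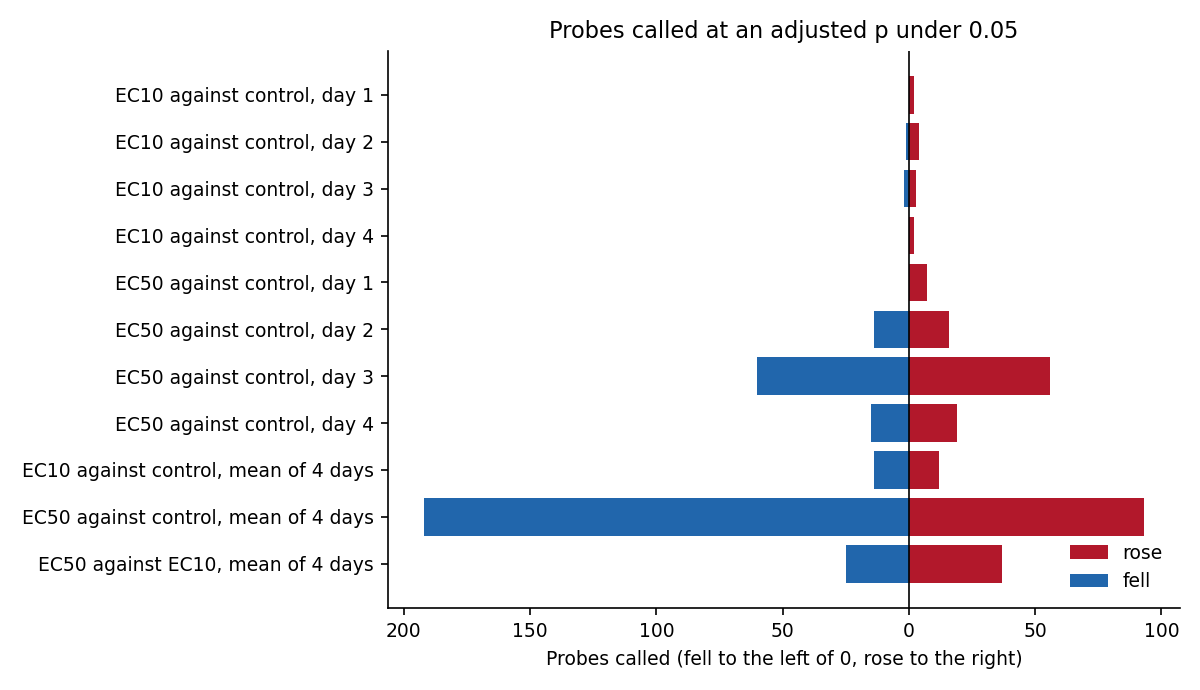
Number of probes called at an adjusted p under 0.05 (x axis; probes that fell to the left of 0, probes that rose to the right) in each comparison (y axis). On single days the EC10 counts are 5 or lower, and the EC50 count is highest on day 3, with 56 that rose and 60 that fell.

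At the EC10, averaged over the 4 days, 26 probes differed from the controls, 12 of which rose and 14 fell. CUST_11333 rose by 2.35 ± 0.21 (adjusted p = 3e-09), and CUST_19204 by 1.43 ± 0.12 (adjusted p = 2.2e-09). CUST_88830 fell by 0.91 ± 0.16 (adjusted p = 0.0064) and CUST_88843 fell by 0.90 ± 0.16 (adjusted p = 0.011). The EC10 changes of both were alike on each day, so they need not stand for separate transcripts. All 12 probes that rose lay above the controls on all 4 days, with medians of 0.87, 0.82, 0.60 and 0.62 by day. All 14 that fell lay below them, with medians of -0.27, -0.36, -0.52 and -0.45. Here too the call on the mean of the same days favours one direction on each day. With slide as a block 35 probes were called, and 92.3 to 100% of the 26 kept their direction within the 5 slides that held pools of both groups, in the pools that had selected them. The count was 5 with the values as deposited (4 rose, 1 fell), 6 with median centring (5 rose, 1 fell) and 8 with array as a block, and 11, 11, 12 and 9 without the pools numbered 1, 2, 3 or 4. Neither of the 2 named falls was called with the deposited or median-centred values, where the change of CUST_88830 was -0.88 and -0.86 and that of CUST_88843 -0.87 and -0.84. Over 16 other fits they were not called in 6 and 8.

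On single days few EC10 probes passed, and the counts were not stable: leaving out 1 pool gave 1 to 2, 3 to 17, 1 to 17 and 0 to 31 probes on days 1 to 4, and on days 3 and 4 other groupings of the same pools reached the real count, in all 4 and 6 of 35. On day 1, CUST_12735 rose by 1.31 ± 0.19 and CUST_4409 by 1.14 ± 0.18, and no other probe was called. On day 2, 4 probes rose, led by CUST_11333 (2.60 ± 0.42) and CUST_11849 (2.42 ± 0.26), and CUST_32994, a probe below an intensity of 64 in every group, fell by 0.44 ± 0.07. On day 3, CUST_11333 (2.32 ± 0.42) and CUST_19204 (1.55 ± 0.25) led the 3 rises, and CUST_22574 fell by 1.02 ± 0.17 and CUST_51228 fell by 0.63 ± 0.11. On day 4, CUST_11333 rose by 2.92 ± 0.42 and CUST_4409 by 1.14 ± 0.18. Of 20 other fits each, 5 called CUST_11333 and 8 called CUST_51228 on day 3, with changes of 2.07 to 2.49 and of -0.80 to -0.47, and all 20 called CUST_11849 on day 2. CUST_4409 was called in all 8 comparisons of a single day. No probe was called for a difference of the EC10 effect between days in limma (lowest adjusted p = 0.11), and median centring and loess each called 1. An unadjusted p under 0.05 in limma was seen for 6844, 7.92% of all. The deposited and the median-centred values called no probe on days 1, 3 and 4. Median centring called 2541 on day 2, and the fit without dim channels called 1410 on day 3.

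The EC50 was then set against the EC10, to ask which transcripts differed between both concentrations. On the mean of 4 days 37 probes were higher and 25 lower at the EC50. CUST_14670 was higher by 1.20 ± 0.19 (adjusted p = 0.0011) and CUST_75596 by 0.85 ± 0.12 (adjusted p = 0.00031). CUST_18519 was lower, with a difference of -0.90 ± 0.13 (adjusted p = 0.00024), and so was CUST_41163, with -0.65 ± 0.14 (adjusted p = 0.044). Against controls the EC10 changes of these 4 probes on that mean were 0.23, 0.02, -0.11 and -0.33, and none was called. For CUST_19204 the difference was 0.84 ± 0.13 (adjusted p = 0.00054), while for CUST_11333, with 0.91 ± 0.21, it did not pass (adjusted p = 0.089). The count moved to 163 with slide as a block and to 17 with the deposited values, of which none was lower at the EC50; 1 of 46 was lower with median centring and 2 of 35 without the dim channels. The count was 33, 7, 8 and 21 without the pools numbered 1, 2, 3 or 4. CUST_41163 was not called in 11 of 16 other fits, with differences of -0.71 to -0.41.

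The zinc comparisons share control pools. Of the 285 probes called at the EC50, 269 had the same direction on the mean of 4 days at the EC10, and 20 of the 26 EC10 probes were among them, 10 of which rose and 10 fell. On days 1 to 4 alone 220, 251, 267 and 197 had the same direction at the EC10, and on day 4 only 37 of the 93 that rose did, with a median of -0.09. Independent lists would share 0.086 probes, 0.013 of those that rose and 0.031 of those that fell, values that do not allow for the shared controls. Across probes, which are not independent replicates, changes on the mean of 4 days correlated between concentrations at 0.57, with a covariance of 0.00375. Simulations of unchanged groups with the same controls gave 0.49 and 0.00254. On days 1 to 4 alone the correlations were 0.31, 0.49, 0.50 and 0.53, against 0.48, 0.50, 0.48 and 0.53 in simulations. The covariances were 0.00399, 0.0111, 0.0147 and 0.016, against 0.00985, 0.0106, 0.00994 and 0.0111. These simulations had no correlation within slides. With the control pools split between the comparisons the correlation on the mean of 4 days was -0.08 and 0.04. The split parts lay mostly on different slides, and samples of one slide deviated together, so slide differences also enter the split values. Of the probes called at the EC50 with split controls, 68.8% of 253 and 96.2% of 52 had the same direction at the EC10.

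In control animals 281 probes differed between the 4 days in the soil. Probe CUST_18359 went from 9.31 ± 0.27 on day 1 to 10.71 ± 0.30, 11.52 ± 0.34 and 11.86 ± 0.22 on days 2 to 4 (moderated F = 97.7, adjusted p = 3.4e-13). CUST_50327 went from 9.53 ± 0.19 to 11.81 ± 0.41, 12.75 ± 0.10 and 13.12 ± 0.26 (moderated F = 93.8, adjusted p = 3.4e-13). Of the 281 probes, 178 were higher on day 4 than on day 1, and day 1 lay farthest from the other days for 178. Day 1 differed from days 2, 3 and 4 at 48, 205 and 245 of all probes, day 2 differed from days 3 and 4 at 2 and 32, and none was called between days 3 and 4. The median size of the change between days 3 and 4 was 0.19 over the 281 probes. With slide as a block 144 probes were called, with array as a block 3, and without the pools numbered 1, 2, 3 or 4 the counts were 100, 83, 177 and 131. The deposited values called 72, median centring 96, loess 251 and sample weights 1217. Control pools of days 1 and 4 shared no slide, so slide differences stay open as part of these changes.

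In zinc animals most of the same probes moved the same way. From day 1 to day 4 the 281 probes changed by a median of 0.76 in the direction of the controls in control animals, 0.64 at the EC10 and 0.48 at the EC50, and 271 and 260 of them kept the direction of the controls at the EC10 and EC50. CUST_18359 reached 11.84 ± 0.11 at the EC10 and 11.50 ± 0.12 at the EC50 on day 4. The control value comes from the pools that selected the probes, and the other values do not. Tested alone, 559 probes differed between days at the EC10 and 153 at the EC50, of which 135 and 75 were among the 281.

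**Figure D3:**
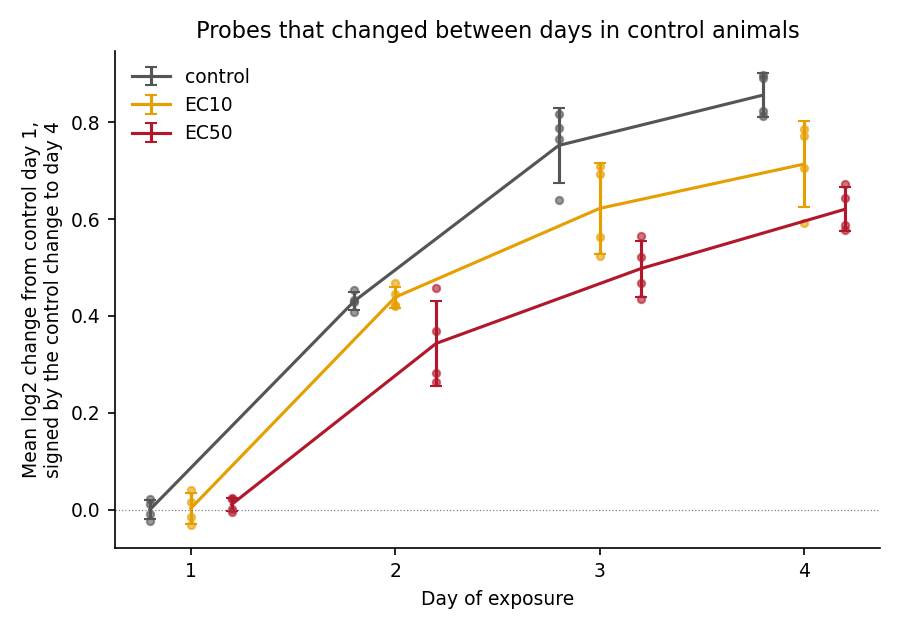
Mean log2 change from control day 1 (y axis) over 277 of the probes that differed between days in control animals, each signed by its control change from day 1 to day 4, for each pool (points) with group means and SD (lines and bars, n = 4), by day (x axis). On day 4 the means are 0.86 in control, 0.71 in EC10 and 0.62 in EC50 animals, and on day 1 they lie between 0 and 0.01.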

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

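The tests of a spread shared by all days and of a response differing between days, both for day 3 below, the bound of 48 for a single pool and the slide block in other splits were chosen after the counts had been seen; the other tests here were chosen before their results. Levels are log2 intensities of 4 pools in a group.

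In 7 of 122 groups of 4 pools of the named probes 1 pool stood apart by Dixon's ratio, where chance gives about 6.1. CUST_11333 was at 5.53 in control pool 3 of day 2 against a mean of 5.18 in the other pools (ratio 0.885). CUST_4409 was at 6.88 in EC10 pool 4 of day 4 against 7.63 (ratio 0.945), and CUST_52260 was at 7.06 in control pool 3 of day 3 against 8.21 (ratio 0.841). CUST_88830 was at 7.37 in EC10 pool 2 of day 1 against 7.83 (ratio 0.902). CUST_19204 was at 7.67 in EC50 pool 1 of day 1 against 8.14 (ratio 0.833). CUST_18519, a bright probe, had 2 such groups: 15.19 in EC10 pool 2 of day 4 against 14.54 (ratio 0.835), and 14.24 in EC50 pool 1 of day 4 against 13.23 (ratio 0.911).

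Every split of 8 pools into 4 and 4 was counted once for the single days, and 100 splits were drawn for the other comparisons. At the EC50 only 1 split of 35, the real one, gave as many probes on each day. The real counts were 7, 30, 116 and 34 and the highest of the other splits gave 1, 5, 5 and 0. The same held at the EC10 on days 1 and 2, with 2 and 5 probes against 0 and 0. A share of 1 in 35 is the smallest this test can give, and several comparisons were tested. Pools were exchanged freely although those of one slide correlate. Other groupings thus did not reach these counts, but the splits do not exclude chance. On days 3 and 4 chance cannot be excluded at the EC10 either, where 4 and 6 of 35 splits gave as many. On day 3 the real count was 5 and another split gave 1812 probes; it set 4 pools on slides 2, 2, 6 and 6 against 4 on slides 3, 5, 5 and 6, with 1 EC10 pool among 3 controls on the first side. On day 4 the real count was 2 and another split gave 125, with pools on slides 2, 2, 3 and 4 against slides 4, 4, 4 and 5. With slide as a block these splits gave 0 and 54 probes and the real ones 4 and 2. The sides of the day 3 split lay apart on the first principal component, at 16.63 to 34.83 against -70.96 to -4.38, and slide accounted for 71.3% of the variance of that component, though slide 6 lay on both sides. The sides of the day 4 split overlapped on it, at -17.14 to 45.89 against -59.36 to 21.10, and what set those pools apart was not found. On the mean of 4 days only 1 of 100 splits, the real one, gave as many probes for EC10 (26, highest other 1), EC50 (285, highest other 3) and EC50 against EC10 (62, highest other 7). No other drawn grouping of the pools thus reached these counts. The same holds for control animals between days, with 281 probes and 166 in the highest other split. For the difference of a zinc effect between days the real count was 0, which every split reaches, so the 100 splits decide nothing here and chance cannot be excluded; the highest of the others gave 5 probes at the EC10 and 1 at the EC50.

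More probes were called for the EC50 than for the EC10. Slide differences as the whole reason are argued against by the fit with slide as a block, which called 322 probes at the EC50 and 35 at the EC10. Dim channels are argued against by the fit without them, with 187 and 17 probes. A response that grows with concentration is consistent with a test on pools not used to pick the probes: 200 probes picked by the EC50 in 2 pools per group had a median EC10 change of 0.13 in the other pools against 0.29 at the EC50, the means of 0.08 against 0.28 when picked in pools 1 and 2 and of 0.18 against 0.30 when picked in pools 3 and 4. Picking by the EC50 favours a larger change at the EC50, so only the EC10 change in the same direction bears on the question. Probes that respond at the EC50 alone were not told apart from a response that grows with concentration. Such growth stays a hypothesis, since it was found and tested on pools of the same experiment.

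On day 3 more probes were called for the EC50 than on other days. Slide differences are argued against by 156 probes with slide as a block, where the next day had 28. A single pool stays open: the lowest day 3 count with a pool left out was 46, above the bound of 34 written before, the full count of day 4, but day 2 reached 48 with a pool left out, and like has to be set against like. Scaling and weights stay open, since days 2, 3 and 4 had 18, 12 and 11 probes with the deposited values and day 4 had 650 against 305 on day 3 with sample weights, and so does a spread shared by all days: with the samples of 1 day in the fit, day 3 had 9 probes and day 2 had 23. A response that differs between days stays open too, and is consistent with 28 of the 285 probes called on the mean of 4 days, whose EC50 effect differed between days when adjusted over that list alone; 21 of them had their largest change on day 3 and 7 on day 4.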

How the results depend on the processing

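Quantile normalization as the setting of all results, loess, leaving out dim channels and estimated sample weights were chosen after seeing the data. Counts follow the order EC10 on days 1 to 4, EC50 on days 1 to 4, EC10 mean, EC50 mean, EC50 against EC10 and control days, with quantile values of 2, 5, 5, 2, 7, 30, 116, 34, 26, 285, 62 and 281. Where a count moved by over 1.5 times the cause was not tested, unless fewer samples or probes entered. Brightness stood in place of depth, with 13.8 to 47.4% of the spots of a channel above an intensity of 64.

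With the values as deposited the counts were 0, 3, 0, 0, 1, 18, 12, 11, 5, 66, 17 and 72. These values moved the median of all probes by -0.17 and 0.13 for the EC10 on days 1 and 2 and by -0.11 and 0.18 for the EC50, and quantile values moved it by 0.01 or less. Median centring gave 0, 2541, 0, 0, 6, 25, 36, 16, 6, 147, 46 and 96, and 1 probe whose EC10 effect differed between days. Loess gave 2, 6, 22, 2, 10, 34, 284, 48, 34, 443, 161 and 251, with 1 and 3 probes whose EC10 and EC50 effects differed between days. The EC50 mean split into 63 that rose and 3 that fell as deposited, 134 and 13 centred, and 200 and 243 with loess, against 93 and 192.

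With only the compared samples in the fit the counts were 0, 3, 0, 1, 1, 23, 9, 16, 18, 356, 25 and 143, and without a dye term 2, 5, 2, 2, 7, 20, 63, 29, 23, 189, 33 and 205. Array as a fixed block gave 0, 4, 0, 1, 8, 9, 62, 12, 8, 124, 23 and 3, and leaving array out of the model gave 2, 4, 2, 2, 7, 20, 50, 24, 23, 163, 20 and 276. Slide as a fixed block gave 2, 3, 4, 2, 9, 28, 156, 26, 35, 322, 163 and 144. Above the median level the counts were 2, 4, 5, 2, 8, 38, 143, 35, 25, 337, 94 and 293, with fewer probes tested. Without the 9 dim channels they were 1, 3, 1410, 2, 7, 8, 62, 23, 17, 187, 35 and 217. Sample weights gave 7, 10, 2, 45, 25, 25, 305, 650, 30, 770, 258 and 1217, and 26 probes whose EC50 effect differed between days.

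Replicate numbers did not pair the samples, since in 0 of 8 comparisons did every pair of one number correlate above 0.1. With the replicate number as a block the counts were 2, 5, 5, 2, 7, 23, 123, 31, 25, 281, 56 and 263, and the block changed no count by over 1.5 times.

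With 1 pool left out, EC10 counts were 1 to 2, 3 to 17, 1 to 17 and 0 to 31 on days 1 to 4, EC50 counts 5 to 8, 14 to 48, 46 to 152 and 16 to 33. With all pools of 1 number left out the counts were 9 to 12 for the EC10 mean, 109 to 168 for the EC50 mean, 7 to 33 for EC50 against EC10, 83 to 177 for control days, and 0 for both differences between days. At the EC10 the count moved by over 1.5 times on day 1 to 1 without EC10 pool 1, 2 or 3; on day 2 to 17 without control pool 3 and to 3 without EC10 pool 3 or 4. On day 3 it moved to 3, 1, 12 and 14 without control pool 1, 2, 3 or 4 and to 2, 3, 10 and 17 without EC10 pool 1, 2, 3 or 4. On day 4 it moved to 0 without control pool 4 and to 4, 1 and 31 without EC10 pool 1, 2 or 3. At the EC50 it moved on day 2 to 19 without control pool 1 or 4 and to 14, 48 and 19 without EC50 pool 2, 3 or 4. On day 3 it moved to 64 and 57 without control pool 1 or 2 and to 46, 75 and 72 without EC50 pool 1, 3 or 4, and on day 4 to 16 without control pool 2 and to 19 without EC50 pool 2.

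The 37 results of named probes that have a direction kept it in all 443 fits of other settings and all 248 with pools left out, and were still called in 336 and 188 of them. The naming rule took the largest called changes that held their direction over all days or all treated pools. The choice of probes thus favoured a kept direction in other fits. The F tests of 2 control-day probes have no direction and were called in all 24 and all 8.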

Other observations

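The comparison of EC50 with EC10 on day 4, the correlation of residuals with slide removed, the time score under other scalings the matched random lists and the overlap with split controls were chosen after the related results had been seen. The other tests here were chosen before theirs.

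The EC10 and EC50 were compared on day 4 for the probes named by the rule. Among them were 4 of the 6 probes called at the EC50 on every day, and the concentrations differed for 3 of these 4. For CUST_11849 the EC10 change was 1.25, 2.42, 1.26 and 0.74 on days 1 to 4 (SE 0.26), and the EC50 change was 2.14, 2.11, 2.04 and 2.52. For CUST_19204 the EC10 change was 1.14, 2.24, 1.55 and 0.80 (SE 0.25), and the EC50 change was 2.05, 2.19, 2.28 and 2.59. On day 4 the EC50 lay above the EC10 by 1.78 ± 0.25 (adjusted p = 0.00026) and 1.79 ± 0.24 (adjusted p = 0.00012), and for CUST_4409 by 1.15 ± 0.17 (adjusted p = 0.00061). For CUST_11333 the difference was 1.03 ± 0.40 (adjusted p = 0.49). The difference of the EC10 effect between days did not pass for CUST_11849 and CUST_19204 (adjusted p = 0.35 and 0.40), and neither did that of EC50 against EC10 (adjusted p = 0.072 and 0.18). CUST_14670 and CUST_75596 were also higher at the EC50 on day 4, by 1.59 and 1.3 (adjusted p = 0.043 and 0.007). CUST_15773, CUST_18519 and CUST_12735 were lower, with differences of -1.36, -1.27 and -0.9 (adjusted p = 0.005, 0.0096 and 0.02). For CUST_88830 and CUST_88843 the EC50 lay above the EC10 on day 4 by 1.73 ± 0.31 (adjusted p = 0.0058) and 1.71 ± 0.31 (adjusted p = 0.0072), but the difference on the mean of 4 days (0.64 and 0.61, adjusted p = 0.16 and 0.22) and its change between days (adjusted p = 0.32 and 0.35) did not pass.

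Some probes were called both for zinc and for a difference between days in control animals. Of the 285 probes called at the EC50 and the 281 that differed between days in control animals, 60 were in both lists, where independent lists would share 0.93 and 1000 random lists matched on level and variance shared at most 11. The EC50 change of all 60 ran against the change of the controls from day 1 to day 4: 55 rose with time and fell with the EC50, and 5 fell with time and rose with it. Both lists used the same 16 control pools, and no value for unchanged groups stands beside the 60 of 60. With control pools 1 and 2 for the days and 3 and 4 for the EC50, 7 probes were in both lists and all 7 ran opposite, and of the 123 control-day probes 67.5% did. With the pools exchanged 10 were in both and 8 ran opposite, and of the 39 control-day probes 56.4% did. Independent lists would share 0.074 and 0.11 probes. Control pools 1 and 2 lay mostly on other slides than pools 3 and 4, so slide differences also enter these values. CUST_18519 was one of the 55, with 12.80 ± 0.25 on day 1 and 14.58 ± 0.21 on day 4 in control animals and 12.55 ± 0.24 and 13.48 ± 0.51 in EC50 animals.

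The change with time may be smaller at the EC50. This was noticed on CUST_16020 and CUST_18519, which were left out together with CUST_18359 and CUST_50327 of a score, the mean signed change from control day 1 over the other 277 control-day probes, and EC10 rather than control pools were the reference because controls had selected the probes. Over days 2 to 4 the score was lower at the EC50 than at the EC10 by -0.10 (two-sided permutation test within days, p = 0.0019), and on day 1 it differed by 0.01 (exact permutation test, p = 0.71). Pools of a day were exchanged freely although those of one slide correlate. On days 2, 3 and 4 alone the difference was -0.10, -0.12 and -0.09 (exact permutation p = 0.11 each, adjusted over 4 days 0.15; the smallest p of 4 against 4 is 0.029). Slide differences are argued against by -0.09 ± 0.013 (SE) with slide as a block. Dim channels stay open, with -0.07 ± 0.026 without them, and so does scaling, since the difference was -0.06 (permutation p = 0.20) with the deposited values, -0.07 (permutation p = 0.082) with median centring and -0.11 (permutation p = 0.0020) with loess.

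For control animals between days, 144 probes were called with slide as a block, 107 of them among the 281, and 217 without dim channels, 182 of them among the 281. Slide differences as the whole reason are argued against by the score of 277 of these probes, which rose within slides in zinc pools. On slide 3 it was -0.032 and -0.014 in EC10 pools of day 1 and 0.706 on day 4. In EC50 pools of slide 5 it was -0.004 on day 1 and 0.577 on day 4. On slide 1 it was 0.022 and 0.024 in EC50 pools of day 1 and 0.588 on day 4. As a part of the change, and for single probes, slide differences stay open. Probes that fell at the EC50 varied together among the 16 control pools around their group means, with a mean pairwise correlation of 0.244 against a 95th percentile of 0.025 in 1000 random sets, and of 0.075 against 0.012 with slide removed. Probes that rose varied together too, with 0.131 against 0.023. Probes with neighbouring numbers had a residual correlation only 0.006 above that of random pairs. Still, of the 285 probes called at the EC50, 77 had a partner with a residual correlation over 0.8. At that limit the 285 formed 221 clusters, so a count of probes need not be a count of transcripts. No such values for random sets of 285 probes stand beside these, and samples of one slide deviated together. Which probes share a transcript was thus not shown.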
